A study of Mus musculus with 14 samples.

How the data were processed

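The labels describe 14 libraries from sorted splenic Ly49H+ NK cells of C57BL/6 mice, grouped by antibody (H3K4me1 or IgG) and by day after MCMV infection (0, 2 or 7). The labels also give a batch letter. Both day 0 H3K4me1 libraries were in batch F, 3 of the 4 day 2 libraries were in batch F and 1 was in batch G, and the 3 day 7 libraries were in batches G (2) and M (1). Day 7 thus shared no batch with day 0. Per the labels' protocols, NK cells were enriched from spleens by depleting other lineages, sorted by surface markers, and libraries were made with a commercial kit and sequenced in pairs of 100-base reads on an Illumina instrument. The protocol text also describes adoptive transfer with sorting of donor cells, and which libraries came from transferred cells is not given in the labels. Replicates are separate samples in the labels, with no statement used here that ties them to separate mice.

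The deposited file was a BED list of 6 columns without a header, holding 1 set of peaks for the whole series. Its name describes narrow peaks, combined over replicates, for NK cells on the 3 days. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Trimmomatic 0.36, MACS2 2.1.1.20160309 and DESeq2 were used on build mm10. The notes used here give these tools no role or order. The aligner, the peak threshold, and the rule by which peaks of different libraries were joined are not given in the sources used here. The score column that the authors deposited held 0 in every row and was not used. Peak positions are as deposited, written here 1-based. By its name the list joins replicates and days, but which libraries it includes is not stated. A long peak may thus be the union of shorter peaks from different libraries, and a peak found on a single day has the same standing as a peak found on all 3. Peaks are numbered up to 30700, and 3382 of these numbers (11.0%) are not among the rows analysed here. No counts per library were analysed here, so depth, signal strength and the precision of each peak are unknown. Columns of samples outside the series numbered 0.

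Genes were taken from the RefSeq annotation of GRCm38.p6, whose primary assembly is mm10. The table gave the chromosome, start, end and type of 49943 genes, of which 21887 are protein-coding. It had no strand, and no genome sequence was used here. The design fixed before the data were examined had planned windows around transcription start sites, exon and intron classes and sequence motifs. Windows around start sites were replaced by an alternative that the design had named, the gene extended by 20 kb on each side, and gene ends stood in for start sites. Exons, introns and motifs were not analysed, and comparisons between days could not be run.

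For each protein-coding gene, the peaks whose midpoint lay in its extended region were counted, together with the bases of the region that any peak covered, including peaks whose midpoint lay outside it. A peak was given to every region that held it, so neighbouring genes could share peaks. The longest peak of a gene is given at its full width and can reach beyond the region. The 15 gene lists were written before the data were examined, and 301 of their 302 entries matched a gene by symbol or synonym (Zfp683 did not). The median count of a list was compared with 10000 random lists of the same size, matched on region length in 10 bins (permutation test, two-sided). Benjamini-Hochberg adjustment ran over the 15 lists, with a threshold of 0.05. The percentile of a gene is its rank by number of peaks within its length bin. In simulations with randomly placed peaks, 21631 genes and random lists of 20 genes, calls were made at an unadjusted p under 0.05. The test called 1% of unchanged lists, 37% of lists with 2 times the peaks and 77% of lists with 3 times the peaks, so it could miss smaller differences. The simulations left out the adjustment over 15 lists, the clustering of the real peaks and lists of neighbouring genes. These rates may therefore not hold for the real lists.

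Positions were compared with 100 random placements that kept each peak's width and chromosome and let no peaks overlap, between the first and the last annotated base of each chromosome. Chromosome Y was left out of these. Assembly gaps and stretches to which reads cannot be mapped were not excluded. Coverage around gene ends used 20 of the placements. Clusters were formed by joining peaks at most 12.5 kb apart and ranked by number of peaks. Intervals are exact binomial or Poisson intervals at 95% and cover counting error only. Peaks per Mb used the annotated length of each chromosome.

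The genes named were fixed by rule before the data were examined. They were 12 genes named in any case (Klra8, Ncr1, Ifng, Gzmb, Prf1, Tbx21, Eomes, Il12rb2, Tcf7, Cd3e, Cd19 and Alb), the 3 genes of each list with the most peaks, and the genes at the 10 largest clusters and the 10 longest peaks. Other genes named, such as those of a list without a peak, were chosen after their values were seen. Alternatives fixed beforehand were other matching, 1 gene per 100 kb, covered bases, the mean, only the peaks at or above the median width, nearest gene only, a 2.5 kb window at gene ends, any overlap, genes of all types, other joining distances, and only peaks far from gene ends. Alternatives chosen after seeing the data were flanks of 5 and 50 kb, windows of 50 kb around both gene ends, matching on length and number of genes, and leaving out peaks of 10 kb or more. A further 27 lists and gene families, and the share of genes with a peak of 10 kb or more (also with limits of 5 and 20 kb and with 1 gene kept per 100 kb), were added after the design was fixed. The definitions of the interferon and cytochrome P450 families were corrected after they were seen to catch Ifnar1, Ifnar2 and Cyp27b1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.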

Results

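The series followed natural killer (NK) cells that carry Ly49H, the activating receptor through which NK cells of C57BL/6 mice recognise mouse cytomegalovirus (MCMV), from the resting state into the response to infection. Sorted splenic Ly49H+ NK cells of wild-type mice were profiled with an antibody against H3K4me1, a histone mark found at enhancers and around promoters, on day 0, day 2 and day 7. The labels describe 14 libraries. Of these, 9 used the H3K4me1 antibody (2 on day 0, 4 on day 2 and 3 on day 7) and 5 used a control IgG (1 on day 0, 2 on day 2 and 2 on day 7). The values analysed here were 1 list of 27318 peaks, joined over replicates and over the 3 days. It gave positions on mm10 but no column for a library, a day or an antibody, and its score was 0 in all 27318 rows. The series names no mark other than H3K4me1 in the labels used here, so the peaks are taken to be H3K4me1 peaks. The list itself does not say so, and the labels name a different H3K4me1 peak atlas, of NK and CD8 T cells, so this remains an assumption. Differences between day 0, day 2 and day 7, and between H3K4me1 and IgG, were therefore not analysed here, there are no values per replicate, and read depth per library is unknown. Batch F held both day 0 H3K4me1 libraries and no day 7 library, so batch and day were also partly confounded in the design. The comparisons below ask where in the genome of these NK cells the marked regions lay, and near which genes. The p-values of the gene lists measure genes against other genes, and no p-value measures the spread between mice.

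The marked regions covered 80.4 Mb. Peak width had a median of 1860 bp, with quartiles of 1033 and 3380 bp and a range of 201 to 82885 bp. Of the peaks, 6491 (23.8%) were 1 kb long or shorter. At the other extreme, 1078 peaks (3.95%) were 10 kb or longer and held 22.5% of all covered bases. Neighbouring peaks lay a median of 12875 bp apart, and none overlapped.

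Peaks gathered in and around genes. The midpoint of 13.7% of the peaks (3731, 95% exact binomial interval 13.3 to 14.1%) lay within 1 kb of an end of a protein-coding gene, against a mean of 3.18% (2.91 to 3.44%) in 100 random placements of the same peaks on their chromosomes. A further 56.0% lay elsewhere inside a protein-coding gene, against 38.9% (38.3 to 39.9%) at random. The share between genes was 30.4%, against 57.9% (57.0 to 58.7%) at random. All 3 observed shares lay outside the range of the 100 placements. Peaks with their midpoint near a gene end were shorter than the rest, with median widths of 1602 and 1910 bp. A long peak that reaches a gene end can have its midpoint farther away, and it then counts with the rest. In all, 7444 peaks had at least 1 base within 1 kb of a gene end. The difference in width may therefore follow from the definition. The gene table used here holds no strand, so a transcription start and a transcription end could not be told apart, and exons, introns and untranslated regions were not analysed here.

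Coverage around gene ends was highest just inside the gene. Among 9976 protein-coding genes of 20 kb or more, with both ends of each counted, a peak covered 13.8% of positions 1 kb inside the gene and 13.9% of positions 2 kb inside. At the annotated end itself the share was 9.61%, and 0.5 kb inside it was 9.20%. Outside the gene the share fell from 8.29% at 1 kb to 5.01% at 5 kb, and random placements gave 3.25% at the end. A peak covered 1 end, but not the other, of 3706 of 21887 protein-coding genes (16.9%), both ends of 554 (2.53%) and neither end of 17627 (80.5%).

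**Figure D1:**
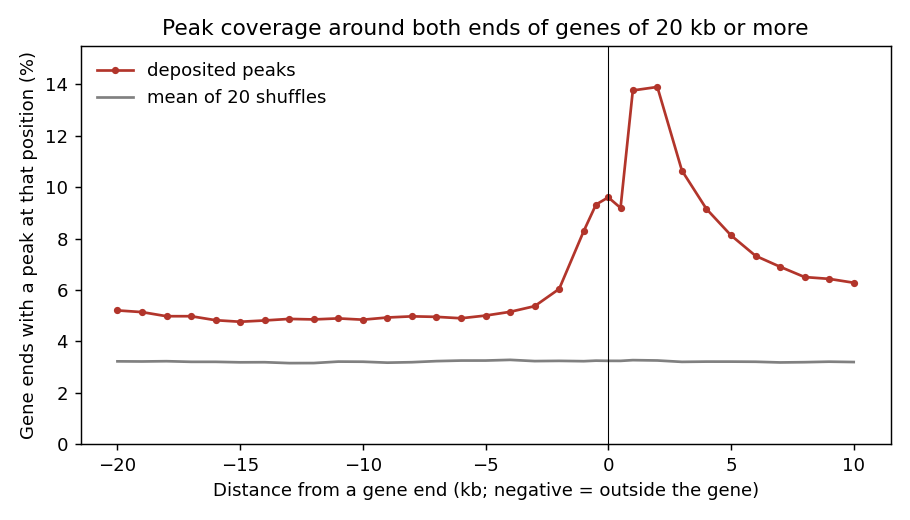
Share of gene ends (y axis, percent) that a peak covers at each distance from the annotated end (x axis, kb, negative outside the gene), for both ends of 9976 protein-coding genes of 20 kb or more. The red line shows the deposited peaks, which reached 13.9% at 2 kb inside the gene and 9.61% at the end, and the grey line shows the mean of 20 random placements, 3.25% at the end.

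The listed NK receptor genes held many more peaks than other genes of similar length. All 26 genes of this list had at least 1 peak in their region (the gene extended by 20 kb on each side), and 12 were in the top 10% of protein-coding genes of similar region length. The median was 4 peaks per gene (quartiles 3 and 5), 3.42 times the mean of 1.17 over random lists of matched genes (permutation test, two-sided, adjusted p = 0.0007, from an unadjusted permutation p of 0.0002, the smallest that these permutations can give). Peaks were counted by their midpoint, and the covered length of a region includes peaks that only reach into it. Itgam, which encodes integrin alpha M, had 9 peaks and 46.0 kb covered. Cd226, encoding the activating receptor DNAM-1, had 9 peaks and 35.2 kb covered, and Itga2, encoding the NK marker CD49b, had 8 peaks and 58.8 kb covered. Klra8 (chromosome 6, 130115226 to 130129898), which encodes Ly49H itself, had 4 peaks and 39.0 kb covered. Ncr1 (chromosome 7, 4337715 to 4345184), encoding the NK receptor NKp46, had 3 peaks and 29.0 kb covered, with a longest peak of 22.6 kb. The Klra genes are close paralogs and their regions overlap, so the placement of reads among them is uncertain, and neighbouring genes counted some peaks in common.

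The transcription factors of the NK lineage stood out to a similar degree. All 20 matched genes had a peak and 7 were in the top 10%, with a median of 6 peaks (quartiles 4 and 7), 4.41 times the mean of 1.36 over matched random lists (permutation test, adjusted p = 0.0007). Tox, an HMG-box factor needed for NK cell development, had 20 peaks and 52.3 kb covered. Runx3 had 10 peaks and 53.9 kb covered, and Prdm1, encoding Blimp-1, had 9 peaks and 42.2 kb covered. Both T-box factors that define mature NK cells were marked. Eomes (chromosome 9, 118478186 to 118486132) had 6 peaks, the longest 6.77 kb, and Tbx21 (chromosome 11, 97098007 to 97115331), encoding T-bet, had 4 peaks and 32.7 kb covered, with a longest peak of 34.9 kb that reached beyond the region.

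The listed genes for cytotoxic effectors and chemokines also held more peaks than matched genes. Of 25 genes, 24 had a peak and 11 were in the top 10%, with a median of 3 peaks (quartiles 2 and 4), 3.35 times the mean of 0.896 over matched random lists (permutation test, adjusted p = 0.0102). Srgn, encoding the granule proteoglycan serglycin, and Stx11, a syntaxin used in granule release, had 6 peaks each, and Tnf had 5. Prf1 (chromosome 10, 61297751 to 61304684), encoding perforin, had 5 peaks and 26.6 kb covered. Ifng (chromosome 10, 118441046 to 118445894), encoding interferon gamma, had 4 peaks and 18.5 kb covered. Gzmb (chromosome 14, 56258836 to 56262334), encoding granzyme B, had 2 peaks, the longest 10.6 kb. Lamp2 was the gene of the list with no peak, and Lamp1 had 1.

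Receptors and signal transducers of the cytokines that activate NK cells had the highest median percentile of the 15 lists, 91.5. All 28 genes had a peak and 16 were in the top 10%, with a median of 5 peaks (quartiles 3 and 6), 3.90 times the mean of 1.28 over matched random lists (permutation test, adjusted p = 0.0007). Stat4, the transducer of interleukin-12 signals, had 10 peaks and 66.4 kb covered. Il21r and Stat5b had 7 each. Il12rb2 (chromosome 6, 67285986 to 67376293), encoding a chain of the interleukin-12 receptor, had 3 peaks and 39.8 kb covered, at the 64.4th percentile of its length class by number of peaks. Jak1 had 4 peaks and 97.2 kb covered.

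Regulators of lymphocyte memory and survival held a median of 4 peaks (quartiles 3 and 6), 3.60 times the mean of 1.11 over matched random lists (permutation test, adjusted p = 0.0007). Of 31 genes, 29 had a peak and 13 were in the top 10%. Bcl2, encoding the survival factor, had 23 peaks and 92.8 kb covered. Bach2, a transcriptional repressor of effector differentiation, had 21 peaks and 52.1 kb covered, and Runx1 had 14 peaks and 99.2 kb covered. Tcf7 (chromosome 11, 52246527 to 52283383), encoding TCF-1, had 4 peaks and 32.5 kb covered. Il7r, encoding the interleukin-7 receptor, and Ly6c1 had no peak. Over these 5 lists together, 127 of 130 genes had a peak and 59 (45.4%) were in the top 10% of their length class.

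The cohesin, housekeeping and cell cycle lists missed the threshold in this test. The median was 4 peaks for 12 genes of the cohesin complex and CTCF (2.56 times matched lists), 2.5 for 16 housekeeping genes (2.40 times) and 1 for 17 cell cycle genes (0.855 times), with permutation adjusted p-values of 0.0656, 0.0975 and 1. The cohesin list was led by Stag1 with 9 peaks, Nipbl with 6 and Stag2 with 5, the housekeeping list by Rpl13a, Eef2 and Tubb5 with 5 each, and the cell cycle list by Aurkb with 6, Pcna with 4 and Top2a with 2. The housekeeping list was past the threshold under 4 of the 11 other settings, and the cohesin list under 2.

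Markers of other lymphocytes and of myeloid cells were mixed. The 20 T cell genes had a median of 3 peaks, 2.38 times matched lists (permutation test, adjusted p = 0.0656), and passed the threshold under 4 of the 11 other settings. Itk (11 peaks), Cd247 (6) and Lck (6), signalling genes that NK cells also use, led that list. Cd3d, Cd3g and Cd28 had 5 each. Cd3e (chromosome 9, 44998735 to 45009663) had 3 peaks and 6.37 kb covered, whereas Cd8a, Cd8b1, Cd4 and Themis had no peak midpoint in their regions. The 19 B cell genes had a median of 1 peak, 0.793 times matched lists (permutation test, adjusted p = 1). Pax5, Fcrla and Cd79a had 4 peaks each, and Cd19 (chromosome 7, 126408448 to 126415148), Ms4a1 and Cd79b had none. The 20 myeloid genes also had a median of 1 peak, against a mean of 0.836 over matched lists (permutation test, adjusted p = 1), with 5 peaks each at Itgax and Elane, 4 at Cd68, and none at Lyz2, S100a8 and S100a9.

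Genes of erythroid cells, hepatocytes, neurons and muscle had few peaks. Of the 67 genes in these 4 lists, 49 had no peak, and the median was 0 in each list. None of the 4 passed the test on the median, whose floor is 0 (permutation adjusted p = 0.760, 0.240, 0.205 and 0.557 for erythroid, hepatocyte, neuronal and muscle genes). On the mean, the erythroid, hepatocyte and muscle lists held 0.259, 0.291 and 0.274 times the peaks of matched lists and passed the threshold, a call that rests on this setting and, for hepatocytes, also on flanks of 50 kb. Alb (chromosome 5, 90460870 to 90476602), encoding serum albumin, had no peak. The best-marked members were Tal1 with 4 peaks, Epor and Hba-a1 with 1 each, Apoa2 and G6pc with 3 each, Fgb with 2, Rbfox3 and Slc17a7 with 3 each, Myod1 with 3, Pln with 2 and Tnnt2 with 1. The exception was Mbp, encoding myelin basic protein, with 12 peaks and 39.8 kb covered.

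**Figure D2:**
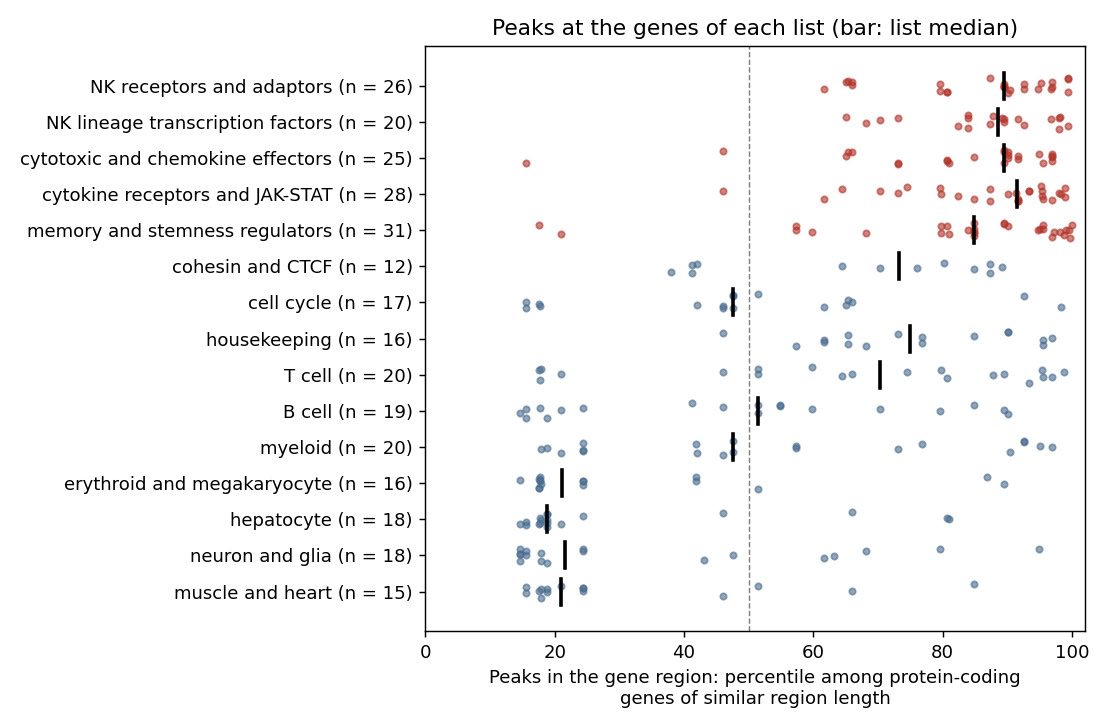
Percentile of each gene (points) by number of peaks in its region among protein-coding genes of similar region length (x axis), for the 15 gene lists (rows, with the number of genes n). The black bar is the list median, red marks the 5 lists past an adjusted permutation p of 0.05, and list medians ran from 91.5 for cytokine receptors and JAK-STAT genes to 18.8 for hepatocyte genes.

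The 10 longest peaks each lay over 1 protein-coding gene. The longest, 82.9 kb, covered much of Jak1 (chromosome 4, 101180985 to 101263869), the kinase shared by many cytokine receptors. The next was a peak of 73.8 kb over Fyn (chromosome 10, 39426187 to 39499989), a kinase of receptor signalling. Peaks of 66.3 kb over Ankrd11, 65.7 kb over Ripor2 and 62.7 kb over Ikzf1, encoding the lymphoid factor Ikaros, followed. The remaining 5 of the top 10 lay over Fam107b (58.1 kb), Chsy1 (57.0 kb), Rapgef1 (54.2 kb), Fli1 (53.7 kb) and Ccdc88c (52.6 kb).

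**Figure D3:**
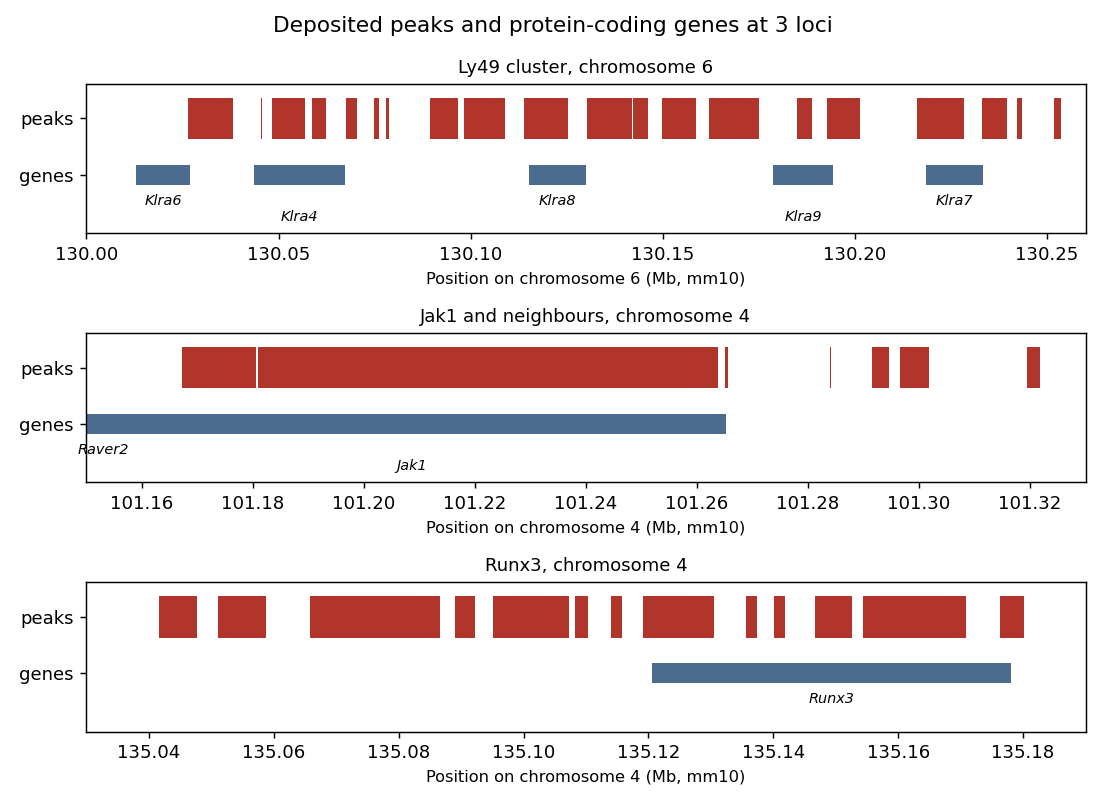
Peaks (red) and protein-coding genes (blue) along 3 loci, with the mm10 position in Mb on the x axis. The panels hold the Ly49 genes around Klra8 on chromosome 6, the longest peak of the list (82.9 kb) over Jak1 on chromosome 4, and Runx3 with the clustered peaks on its left on chromosome 4.

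Peaks also clustered along the chromosomes. After neighbouring peaks were joined, 129 clusters held 10 or more peaks each, with 1500 peaks (5.49%) in all, whereas none of 100 random placements gave such a cluster. The placements took no account of genes, so they cannot tell clustering from the gathering of peaks in and around genes. The count depended strongly on the joining distance, with 4 clusters at 5 kb and 404 at 25 kb, where random placements gave at most 2. The cluster with the most peaks was the array of 5S ribosomal RNA genes on chromosome 8 (123538625 to 123623367), where 23 peaks touched 33 of 48 annotated ribosomal RNA genes. These copies are near-identical, so placement of reads among them is uncertain. The second cluster, 20 peaks over 202 kb, lay at Rap1b and Nup107 on chromosome 10. A cluster of 19 peaks on chromosome 19 spanned 15 protein-coding genes, among them Pitpnm1 and Aip. A cluster of 17 peaks on chromosome 2 (128365737 to 128504145) contained Morrbid, a long noncoding RNA known to control Bcl2l11, and its nearest protein-coding gene was Spdye4c, 87055 bp away. Another 17 peaks lay inside Atp10a. The Ly49 locus was the sixth cluster (chromosome 6, 130026491 to 130201348), with 16 peaks covering 61.9% of 175 kb that held Klra4, Klra8 and Klra9 and touched the end of Klra6. The other 4 of the top 10 were at H2-D1 and Nfkbil1 (16 peaks), Csf2 (16), Septin1 and Zfp771 (15) and Tnfaip3 (15), the last encoding the NF-kB inhibitor A20.

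Peak density differed between chromosomes, and chromosome X was sparse. Autosomes ranged from 7.95 peaks per Mb on chromosome 3 (95% Poisson interval 7.52 to 8.40) to 17.3 on chromosome 11 (16.6 to 18.0). Chromosome X had 405 peaks, or 2.37 per Mb (2.15 to 2.62), which was 0.217 times the autosomal density of 10.9 (95% exact interval of the ratio 0.196 to 0.239). The median width of its peaks, 1842 bp, was close to the 1860 bp of all peaks. Chromosome Y had 4 peaks. Among these, 1 overlapped Uty and 1 overlapped Ddx3y, both genes expressed broadly in male cells, and the other two lay near the far end of the chromosome, where the nearest protein-coding gene was Gm52481. These intervals cover counting error only.

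**Figure D4:**
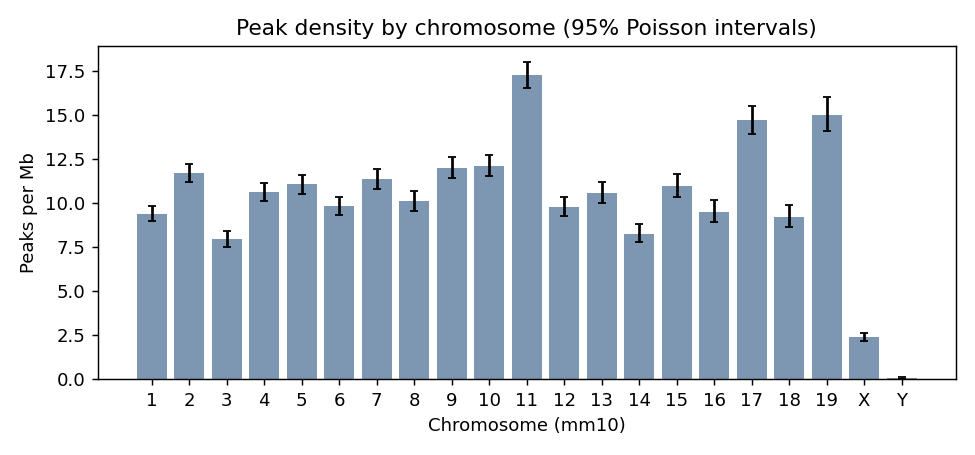
Peaks per Mb of annotated length (y axis, starting at 0) for each mm10 chromosome (x axis), with 95% Poisson intervals as error bars. Chromosome 11 stood highest at 17.3, chromosome X was at 2.37 and chromosome Y at 0.044.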

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

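The flanks of 5 and 50 kb, the windows of 50 kb around both gene ends, the matching on gene number, the removal of long peaks and all alternatives for long peaks were chosen after seeing the data. The list combines replicates and days, so depth per library could not be weighed and no library could be left out. No paired analysis was possible because the peak list has no values per sample. The windows of 20 and 100 kb around transcription start sites, the motif alternatives and all alternatives for comparisons between days were not run. Each of the 5 NK-related lists stayed above matched genes and past the threshold under all 11 alternatives, with ratios from 2.35 to 19.0 and a highest permutation adjusted p of 0.0351. The highest ratio, for effectors with the longer peaks, set a median of 3 against a mean of 0.158 over matched lists, close to the floor. On the mean, the 5 ratios ran from 2.35 to 3.08. All 3 position classes kept their direction outside the random range. The density ratio of chromosome X to the autosomes was 0.214 with only peaks at or above the median width, against 0.217. The other lists moved as follows, as ratios to matched lists, and the causes were not tested. A list is called reversed where its ratio moved from one side of 1 to the other. No reversed list was past the threshold, either in that setting or in the main one, so the reversals are not evidence of a change. Without matching, the cohesin list (3.76) and the T cell list (2.96) passed and the myeloid list reversed (0.980). With covered bases, the cohesin (3.81) and housekeeping (3.32) lists passed and the cell cycle list reversed (1.04). With the mean, the housekeeping (1.91), T cell (1.66), erythroid (0.259), hepatocyte (0.291) and muscle (0.274) lists passed, so 3 lists were below matched genes where the median gave 0. With only peaks at or above the median width, the myeloid list reversed (0). With each peak given to its nearest gene, the housekeeping (5.37) and T cell (4.05) lists passed and the cell cycle (3.43) and myeloid (0) lists reversed. With flanks of 50 kb, the hepatocyte list passed (0), which made 1 list below matched genes, and the myeloid list reversed (0.494). With flanks of 5 kb, the housekeeping list passed (4.35) and the cell cycle (1.77) and B cell (1.53) lists reversed. With 50 kb around both gene ends, the T cell list passed (2.47) and the myeloid (0.428) and muscle (1.16) lists reversed. Clusters of 10 or more peaks numbered 4 at a joining distance of 5 kb, 404 at 25 kb and 59 with only peaks farther than 2.5 kb from a gene end, against 129. For long peaks, the 5 NK-related lists stayed past the threshold in all 3 alternatives, and 2 other lists came to pass it, the cohesin list with a limit of 5 kb (3.13) and the T cell list with 1 gene kept per 100 kb (4.72). A limit of 5 kb reversed the housekeeping list (2.13), and a limit of 20 kb reversed the cohesin, T cell and myeloid lists (0 each).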

Other observations

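The 4 tests of the NK-related lists, the 3 tests of chromosome X and the test of B cell genes were set out before their own results were seen. The patterns that they address were already known from the main results. Because these tests use the same peaks as the main results, they are not independent support. The gene families, the further lists and the comparison of long peaks were chosen after the data were first examined, and the ribosomal RNA array was noticed in the data.

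Long peaks were more frequent at NK-related genes than at length-matched genes. A peak of 10 kb or more lay in the region of 66 of the 130 genes of the 5 NK-related lists (50.8%), against 4.95% of all protein-coding genes. The share was 69.2% for NK receptors (18 of 26 genes) and 14 of 20 lineage transcription factors had one, where length-matched lists gave 4.48% and 6.92% (permutation test, adjusted p = 0.0006 for each, from an unadjusted permutation p of 0.0002, the smallest these permutations can give). It was 44.0% for effectors, 46.4% for cytokine receptors and JAK-STAT genes and 32.3% for memory regulators, each past the threshold at the same permutation adjusted p. Neighbouring genes can count the same long peak, but with 1 gene kept per 100 kb, 12 of 17 receptor genes still had one and all 5 lists stayed past the threshold. Long peaks were not confined to these lists. They lay at 4 of 20 T cell genes, 3 of 12 cohesin genes and 2 of 20 myeloid genes, 3.75, 3.20 and 3.02 times matched lists (permutation adjusted p = 0.0945, 0.251 and 0.528). The T cell list passed with 1 gene kept per 100 kb, and the cohesin list with a limit of 5 kb. No housekeeping, cell cycle, B cell, erythroid, hepatocyte, neuronal or muscle gene had such a peak, where matching gave between 0.588 and 1.23 genes per list, so that these zeros were not past the threshold (permutation adjusted p of 0.923 or above). Klrc1 and Klrc2 shared a peak of 40.6 kb, and Klrg1, a marker of mature NK cells, had one of 28.4 kb.

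Among 27 further lists and families, 5 held more peaks than matched genes after adjustment. These were antigen receptor and ITAM signalling genes (median 6.5 peaks, 4.36 times matched lists, permutation adjusted p = 0.0018), AP-1 and NR4A factors (4 peaks, 3.90 times, permutation adjusted p = 0.0018), the NF-kB pathway (5 peaks, 3.85 times, permutation adjusted p = 0.0018), RUNX factors (14 peaks, 6.14 times, permutation adjusted p = 0.0151) and Hox genes (3 peaks, 3.54 times, permutation adjusted p = 0.0027). Of the AP-1 and NR4A list, 9 of 16 genes also stood in a list above, as did 2 of 3 RUNX genes and 3 of 20 ITAM genes, and none of the NF-kB or Hox genes did. Nfkb1 had 14 peaks and 61.2 kb covered. Chemokine receptors, interferon-stimulated genes, STAT factors and the killer lectin-like receptors outside the Klra family had medians of 3, 2.5, 5 and 3 peaks and missed the threshold (permutation adjusted p = 0.0768, 0.0982, 0.0567 and 0.0702). The whole Ly49 (Klra), granzyme and SLAM families also missed it, at 2.41, 1.62 and 1.49 times matched lists (permutation adjusted p = 0.139, 0.714 and 0.952). CC chemokines, at 1.36 times matched lists, missed it too. No peak lay in the region of 2 of 13 Klra genes, 4 of 10 granzymes and 9 of 19 CC chemokines. Of these 3 families, 6, 5 and 3 genes stood in a list above. A peak lay in the region of 43 of 1110 olfactory receptor genes and 8 of 353 vomeronasal receptor genes. Over all protein-coding genes, without matching on length, the share was 59.0%. The test on the median could not judge these 2 families, because the families and all matched lists stood at 0 (permutation adjusted p = 1 for each).

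The Hox result rests on 4 loci, since neighbouring genes count the same peaks, and its p-value is too small for that reason. Of the 39 genes, 33 had a peak in their region. The Hoxb cluster on chromosome 11 (96194316 to 96368254) held 12 peaks, with 16.0% of its length covered, the Hoxa cluster on chromosome 6 (52155367 to 52260880) 8 peaks, with 23.7% covered, the Hoxc cluster 6 peaks, with 9.48% covered and the Hoxd cluster 4 peaks, with 5.22% covered.

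The excess of peaks at NK-related genes was set against technical explanations. With 1 gene kept per 100 kb, all 5 lists remained past the threshold, which argues against genes lying side by side and counting the same peaks. Matching on region length and on the number of genes also left 5 of the 5 past it, which argues against gene-dense neighbourhoods. The median percentile of the 130 NK-related genes, 89.4, exceeded that of the 45 housekeeping, cell cycle and cohesin genes by 24.1 points (permutation test, two-sided, p = 1e-05, the smallest these permutations can give). This pool cannot stand for genes active in most cells, because gene activity was not measured. Its 17 cell cycle genes had a median percentile of 47.5, against 73.2 for the cohesin genes, and so widened the gap. The 16 housekeeping genes alone were closer, 14.4 points below the NK-related genes (permutation p = 0.00696). That smaller gap argues against peaks gathering alike at NK-related and housekeeping genes, and other genes active in most cells were not tested. The NK-related genes exceeded B cell, myeloid and erythroid genes by 47.5 points (permutation p = 1e-05, the smallest possible), which goes with the hypothesis that the list reflects the identity of the sorted cell. T cell genes, with a median percentile of 70.2, were not part of that comparison. The comparison therefore cannot tell NK identity from an identity shared with T cells. The 5 lists also hold genes that are not particular to NK cells, such as Jak1, the kinase shared by many cytokine receptors. Genes of the NF-kB pathway, none of them in these lists, held 3.85 times the peaks of matched lists. Marking of genes used in many cell types was thus not set apart from NK identity. The percentile comparisons treated all 130 NK-related genes as independent. Neighbouring genes count some of the same peaks, so the p-values of these comparisons are too small. The comparisons were not repeated with 1 gene kept per 100 kb, a step that left 17 of the 26 receptor genes. Mappability and sequence content were not tested.

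Chromosome X was sparse by every measure tried. Its peaks per protein-coding gene were 0.322 times those of the autosomes (95% interval 0.291 to 0.355), which argues against fewer genes as the whole cause. With the absent peak numbers counted back in, the density ratio was 0.251 (0.230 to 0.274). This step could not have brought the ratio to 1, since only 121 numbers were absent on X, beside 405 peaks. Without olfactory, vomeronasal and unnamed Gm or Rik genes, the share of genes with a peak in their region was 26.5% on X and 68.0% on autosomes, a ratio of 0.390 (0.347 to 0.438). The genes removed thus do not account for it, but multicopy families with other names stayed in and were not tested. A lower copy number of X in male cells stays open and untested, since the labels used here do not give the sex of the mice, and the peaks at Uty and Ddx3y on chromosome Y lie in genes with close paralogs on X.

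B cells left in the sort could have brought peaks at B cell genes. The 10 genes with B cell functions that NK cells do not use (Cd19, Ms4a1, Cd79a, Cd79b, Cd22, Pax5, Ebf1, Cr2, Vpreb3 and Fcer2a) had a median percentile of 53.2, close to the middle of their length classes (permutation test, two-sided, p = 0.809). Cd19, Ms4a1 and Cd79b had no peak, and Cd79a and Cd22 had 4 and 3. The test does not decide, because a list joined over replicates and days gives no signal height by which a small share of other cells could be judged. The protocol depleted CD19-positive cells and excluded them again in the sort.

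The absent peak numbers were not spread evenly. On chromosome X, 23.0% of the numbers were absent, against 10.8% on the autosomes, where single chromosomes ranged from 8.11 to 13.9% (Fisher's exact test, two-sided, p = 2.3e-15, over numbers and not over samples). Where a single number was absent, the peaks on either side lay a median of 43677 bp apart, against 35280 bp around a single peak that was present. The 5S ribosomal RNA array, with a peak at 33 of 48 annotated genes, contrasted with the 15 ribosomal RNA genes elsewhere, of which 1 overlapped a peak.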
